A study of Rattus norvegicus with 12 samples.

How the data were processed

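RNA-seq values of 12 libraries were analysed, 3 in each of 4 groups defined by the sample labels: control (0 h) and 1.5, 3 and 6 h with 10 µM PT109B. Per the labels' protocols, total RNA was extracted with TRIzol from primary midbrain astrocytes of newborn Sprague-Dawley rats, and libraries were made with the NEBNext Ultra RNA kit. The deposited table gives an estimated count (expected count) and an FPKM value per gene and library, made by the authors per the file headers, with gene symbols and annotation text. StringTie 2.2.1 is named in the submitters' processing notes. The aligner, genome build and annotation are not given in the sources used here. Of the count values 9.49% were not whole numbers, in 1343 genes, so they were taken to be estimated counts and rounded for the count tests, although whole counts had been assumed when the tests were chosen. The deposited FPKM values entered only alternative tests and an estimate of relative depth, taken from the ratio of count to FPKM in genes with counts of at least 200 and FPKM of at least 2, which ranged from 0.892 to 1.20 between libraries.

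The table held 9721 genes, part of those a rat genome has, and genes such as Gapdh, Slc1a3, Junb, Th and Ddc were not analysed here. Of 183 genes with a mean count under 5, 99.5% differed between libraries beyond Poisson noise, where 5% would by chance. Of 34 ribosomal protein genes looked for, 2 were in the table, against 25 of 25 mitosis genes and 25 of 26 immediate early genes. Genes chosen for differing between libraries would give such a table, but the rule of choice is not known. Adjusted p-values, the scaling and the tests of gene lists and terms therefore refer to this set of genes and are not transcriptome-wide. There were 60 genes without a symbol and 58 symbols on more than 1 line, for which the gene with the highest mean count was used. Of the symbols, 9155 were found in a RefSeq gene table of another build (GRCr8), used for names only, and no coordinates are given. Counts from near-identical gene copies or overlapping genes may have been split by the counting, which was not checked.

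Counts were tested in R 4.3.3 with edgeR 4.0.16. After filterByExpr, which removed 230 genes, 9491 genes were scaled by TMM and tested with the robust quasi-likelihood test in 1 fit to all 12 libraries with the group as the only term. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed. Levels are CPM on TMM-scaled library sizes, log2 fold changes use a prior count of 0.125, and SE was derived from the log2 fold change and the F value. Total counts were 9368972 to 12498050 per library. On simulated counts with the spread of these libraries, edgeR recovered 36.1%, 38.8% and 41% of genes changed 2-fold and 83.8%, 79% and 79% of those changed 4-fold at 1.5, 3 and 6 h, with 5, 4 and 11 false calls among 9413, 9407 and 9414 genes. Each gene was drawn independently, so these counts do not cover differences between libraries of a group that many genes share.

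Gene lists (46, with 901 members, 674 of them in the table) were fixed before the data were examined, as were the tests, the groups and the rule for named genes. The lists covered cell identity, signalling, stress, metabolism, cell cycle and markers of other cell types, and 44 with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation of 0.01, prior count of 2), adjusted over lists. In the simulation a list of 20 genes raised 2-fold was called at 3 h, and 0 of 20 unchanged lists were called by camera. Genes were drawn independently there and lists at random, so it does not show how often camera calls unchanged lists whose members move together. With an estimated correlation no list passed at any time. Genes named in the text are the 12 risen and 12 fallen genes with the largest fold change per time among those called, with a mean CPM of at least 2 in the higher group and no overlap between groups. They also include up to 4 called and 2 uncalled members per list and a fixed set of astrocyte, neuronal and early response genes. Enrichment of GO terms of 10 to 500 genes among called genes was tested with Fisher's exact test against the 8441 tested genes with terms.

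Alternatives were other scaling (RLE, upper quartile, library size), other filters, the replicate number as a block, fits of only 2 groups, non-robust fits, a fold threshold of 1.2 (glmTreat), thinned counts, DESeq2 1.42.0, limma-voom and limma-trend on log2 FPKM with pseudocounts, and leaving out each replicate. Scaling by depth from count and FPKM, the microglia level as a covariate, sets of libraries with higher or lower microglia levels and a fixed TMM reference library were added after seeing the data. Replicate numbers were taken from the labels, which do not say that they mark shared cultures, and the main tests do not use them.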

Results

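RNA was sequenced from primary astrocytes of the midbrain of newborn rats, grown with fetal bovine serum, after exposure to 10 µM of PT109B, a small molecule known here only by its code name. There were 12 libraries in 4 groups of 3, namely a control group at 0 h and treated groups at 1.5, 3 and 6 h. The series belongs to work on turning astrocytes into dopaminergic neurons with this compound, and the comparisons ask which transcripts differ from control at each time and between times. Count totals per library ran from 9368972 to 12498050 over the 9721 genes of the table. The table held part of the genes, so several classical markers such as Th, Slc6a3, Pitx3, Foxa2, Lmx1a and Neurog2 were not analysed here. Levels below are mean CPM, counts relative to scaled library size, ± SD over 3 libraries, and changes are log2 fold changes ± SE against control, from a fit to 9491 genes. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

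The control libraries resembled each other (r of 0.989 to 0.995 across genes). In each treated group a pair of libraries was nearly alike (r = 0.995) and 1 stood apart (r of 0.918 to 0.958). Among controls replicate 3 also differed more, though less far (r = 0.9895 and 0.9887, against 0.9949 between replicates 1 and 2). The treated library standing apart was the one closest to the controls. At 1.5 h its r with controls was 0.9757 to 0.9816, against 0.9073 to 0.9309 for the pair. These were 0.9644 to 0.9683 against 0.9252 to 0.9301 at 3 h, and 0.9558 to 0.9575 against 0.9197 to 0.9217 at 6 h. The mean level of 17 microglia markers was 6.77, 6.81 and 7.04 (log2 CPM) in the controls. At 1.5 h it was 3.85 and 3.78 in replicates 1 and 2 and 7.13 in replicate 3. At 3 h replicate 3 had 6.89 against 6.33 and 6.28, and at 6 h replicate 1 had 6.68 against 6.16 and 6.09. Genes of mitosis split the later groups further, with levels in the library standing apart above the other pair by 2.86 (log2) at 3 h and by 3.12 at 6 h. Immediate early genes were above control on both sides of this split, since all 25 measured members lay above the highest control in each of the 9 treated libraries, although at 3 h their level was 6.01 in replicate 3 against 7.03 and 7.06.

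**Figure D1:**
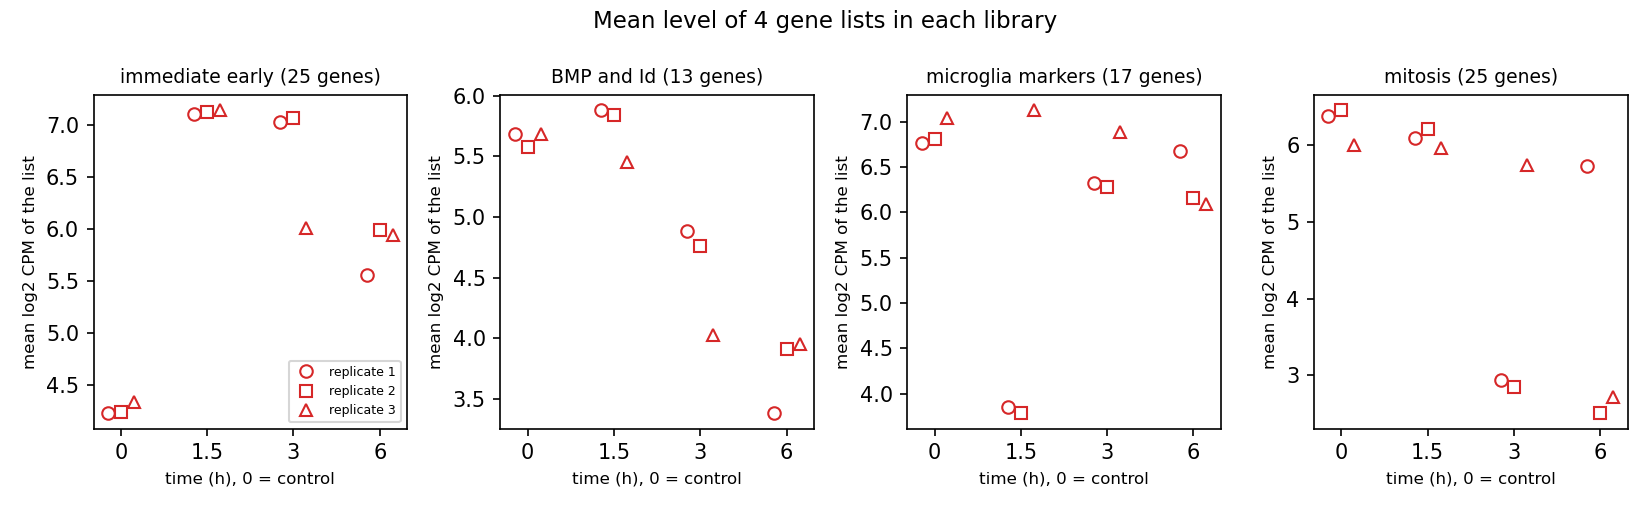
Mean log2 CPM of 4 gene lists in each library, plotted against hours with 10 µM PT109B (0 is control). Each symbol is 1 library and its shape gives the replicate number. The immediate early level was 4.23 to 4.34 in controls and 5.56 to 7.14 in treated libraries, while the microglia level separated replicate 3 from the other pair at 1.5 h and the mitosis level separated 1 library from the other pair at 3 and 6 h.

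At 1.5 h immediate early genes were among the genes with the largest rises. They encode transcription factors and signalling regulators made within minutes of a stimulus. Egr1 (ENSRNOG00000019422) went from 33.7 ± 9.74 to 1080 ± 57.8 CPM, a log2 change of 5.00 ± 0.41 with an adjusted p of 8.72e-05 in edgeR's quasi-likelihood test. Fosb rose from 0.868 ± 0.446 to 92.2 ± 24.7 CPM and Nr4a1 from 5.08 ± 1.45 to 316 ± 74.0 CPM (log2 changes of 6.74 ± 0.74 and 5.96 ± 0.81, n = 3 each). Arc rose by 5.65 ± 0.36 on the log2 scale. Of the immediate early list, 22 of 25 tested members rose (24 rose adjusted over the list alone, camera adjusted p = 1.08e-32, and adjusted p = 0.0692 with an estimated correlation). Fos rose by 3.20 ± 0.28 and Myc by 1.09 ± 0.11 on the log2 scale.

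Some growth factor and ERK pathway genes rose with them. Lif, a cytokine of the interleukin 6 family, went from 54.4 ± 2.81 to 1003 ± 173 CPM (log2 4.21 ± 0.24), and Hbegf, a ligand of the EGF receptor, from 110.3 ± 13.9 to 642 ± 81.5 CPM (2.54 ± 0.15). Among neurotrophic factors 5 of 18 tested members rose (6 rose adjusted over the list alone, camera adjusted p = 1.7e-05, and adjusted p = 0.0692 with an estimated correlation), including Pdgfb (2.79 ± 0.23) and Vegfa (1.02 ± 0.12). The ERK feedback list holds transcripts that follow ERK activity, Hbegf among them, and not only inhibitors of the kinase cascade. Of this list 7 of 15 tested members rose (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.07e-09, and adjusted p = 0.0692 with an estimated correlation). Dusp5, a phosphatase that acts on ERK, rose by 3.46 ± 0.36, and Spry4, an inhibitor of receptor tyrosine kinase signalling, from 68.3 ± 5.71 to 274 ± 76.4 CPM. In the list of cAMP and CREB targets 5 of 17 tested members rose (9 rose adjusted over the list alone, camera adjusted p = 3.25e-05, and adjusted p = 0.369 with an estimated correlation). Of short-lived mRNAs 12 of 22 tested members rose (16 rose and 3 fell adjusted over the list alone, camera adjusted p = 1.55e-10, and adjusted p = 0.206 with an estimated correlation). Several lists share members, so their calls are not independent. The immediate early genes Myc, Btg2, Ier2 and Zfp36 are also in the short-lived list, and Btg2 is among p53 targets. Fosl1 is in the ERK feedback list as well. Nr4a1, Nr4a3 and Dusp1 are among CREB targets, and Dusp1 among glucocorticoid targets. Hbegf is in the ERK feedback and neurotrophic lists. The repressor Hes1, a Notch target, rose by 3.18 ± 0.30, from 10.6 ± 0.390 to 95.7 ± 5.19 CPM, while the Notch list did not pass the test (camera adjusted p = 0.0949).

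Other genes were lower at 1.5 h. Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell from 19.7 ± 1.87 to 2.48 ± 0.322 CPM (log2 -2.98 ± 0.24). The transcription factor Cebpd changed by -1.40 ± 0.22 (log2), and Fam13b and Ppp1r10 by -1.08 ± 0.10 and -1.05 ± 0.12. Among clock genes, Per2 (1.63 ± 0.14) and Ciart (2.34 ± 0.36) were higher. In that list 4 of 14 tested members rose and 1 fell (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0162, and adjusted p = 0.407 with an estimated correlation), and its camera call was lost without replicate 3 of the 1.5 h group or the 3 treated libraries of higher microglia level.

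In all, 315 genes changed at 1.5 h against control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p below 0.05, 185 higher and 130 lower, of which 147 changed 2-fold or more (129 higher and 18 lower). When libraries were scaled by the depth implied by the deposited FPKM values, 168 genes were higher and 217 lower. Without replicate 3 of the 1.5 h group, the library with control-like microglia markers, 2871 genes were called, and leaving out another of the 6 libraries compared gave 115 to 129. With the replicate number as a block 201 genes were called.

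Some lists of stress and structural genes were also called by camera at 1.5 h with the preset correlation. For the integrated stress response 4 of 21 tested members rose (4 rose adjusted over the list alone, camera adjusted p = 0.000102, and adjusted p = 0.407 with an estimated correlation), with Ppp1r15a, which reverses the phosphorylation of eIF2α, at 2.64 ± 0.28. For p53 targets 5 of 18 tested members rose (7 rose adjusted over the list alone, camera adjusted p = 2.37e-05, and adjusted p = 0.385 with an estimated correlation). For TGF-beta targets 2 of 17 tested members rose (4 rose adjusted over the list alone, camera adjusted p = 0.00595, and adjusted p = 0.108 with an estimated correlation). For glucocorticoid targets 5 of 14 tested members rose and 1 fell (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0127, and adjusted p = 0.401 with an estimated correlation). For YAP and SRF targets 2 of 23 tested members rose (2 rose adjusted over the list alone, camera adjusted p = 2.2e-05, and adjusted p = 0.491 with an estimated correlation). For cholesterol synthesis 2 of 16 tested members rose (2 rose adjusted over the list alone, camera adjusted p = 0.0223, and adjusted p = 0.776 with an estimated correlation). For extracellular matrix genes 0 of 22 tested members were called (5 rose adjusted over the list alone, camera adjusted p = 0.000349, and adjusted p = 0.401 with an estimated correlation). Some lists of other cell types were called by camera in the same comparison. Microglia markers had a median log2 change of -1.12, oligodendrocyte lineage markers of 0.99 and fibroblast and meningeal markers of 1.27, and no single member of these 3 lists was called (camera adjusted p = 1.7e-05, 0.00474 and 0.00217, and adjusted p = 0.491, 0.400 and 0.416 with an estimated correlation). The calls of the YAP and SRF, matrix, microglia, oligodendrocyte and fibroblast lists were lost when the microglia level was a covariate and when the 6 libraries with lower microglia levels were left out, and the direction turned in at least 1 of these settings for the YAP and SRF, microglia and oligodendrocyte lists. The TGF-beta call was lost without those 6 libraries and the cholesterol call without replicate 3 of the 1.5 h group or the 3 treated libraries of higher level.

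**Figure D2:**
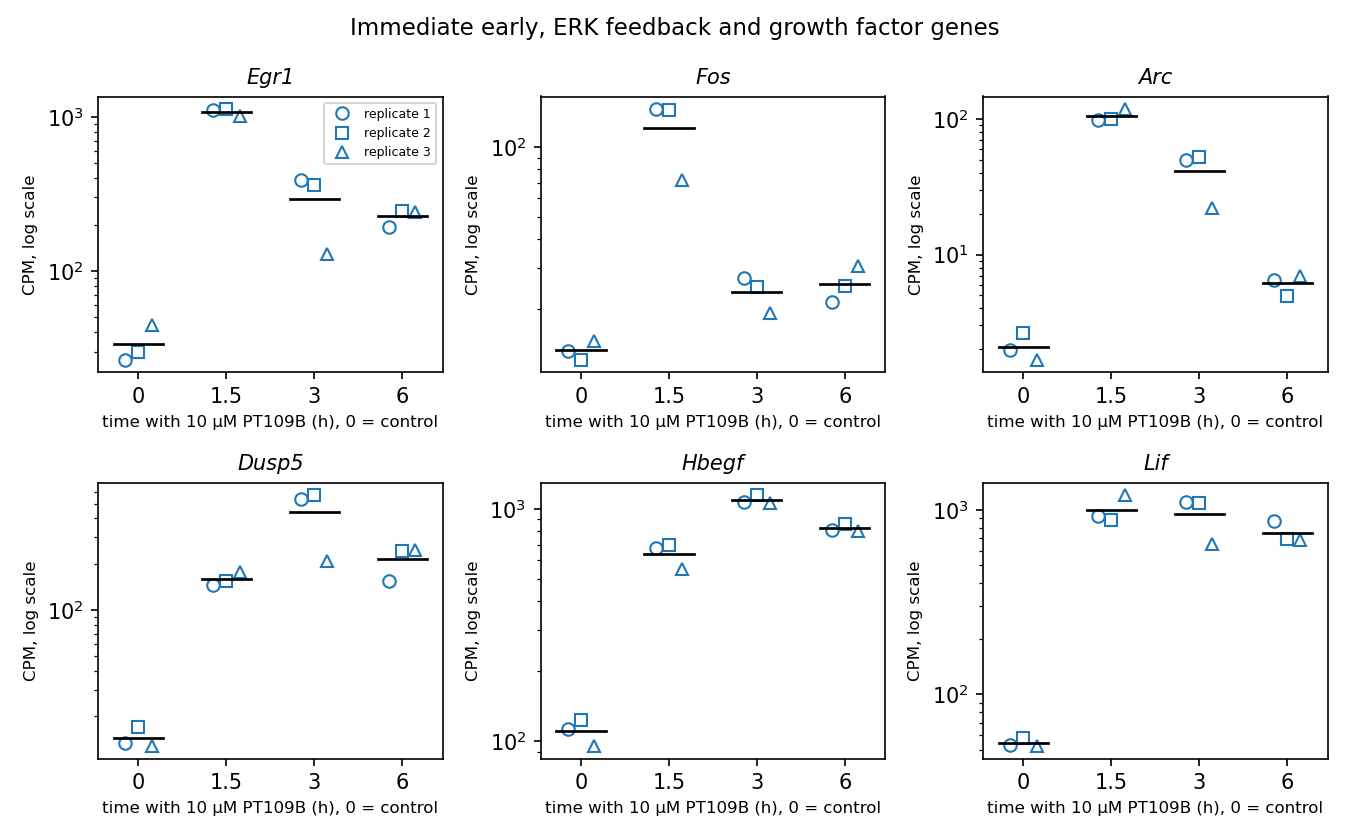
CPM on a log scale of 6 genes in each library against hours with 10 µM PT109B (0 is control). Symbols are libraries, with shapes for the replicate number, and the line is the group mean. Egr1, Fos and Arc were highest at 1.5 h, and Dusp5 and Hbegf at 3 h.

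At 3 h genes of the ERK feedback and neurotrophic factor lists were again called higher, and 754 genes fell. Dusp5 reached 437 ± 198 CPM against 14.4 ± 2.23 in controls (log2 4.92 ± 0.38), Hbegf 1094 ± 43.8 CPM (3.31 ± 0.15) and Dusp4 163 ± 14.9 CPM (3.76 ± 0.34). Of the ERK feedback list 12 of 15 tested members rose (12 rose adjusted over the list alone, camera adjusted p = 9.33e-09, and adjusted p = 0.105 with an estimated correlation). Of immediate early genes 24 of 25 tested members rose (25 rose adjusted over the list alone, camera adjusted p = 1.01e-17, and adjusted p = 0.213 with an estimated correlation). Among neurotrophic factors 9 of 18 tested members rose (11 rose adjusted over the list alone, camera adjusted p = 1.77e-05, and adjusted p = 0.105 with an estimated correlation). Kcnk3, a potassium channel, rose from 1.91 ± 1.01 to 59.0 ± 2.69 CPM (4.94 ± 0.39), and Gdf15, a stress-induced cytokine, from 66.6 ± 8.81 to 747 ± 351 CPM (3.49 ± 0.39).

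The genes that fell at 3 h included targets of bone morphogenetic protein (BMP) signalling. Id3, an inhibitor of basic helix-loop-helix factors, fell from 475 ± 31.4 to 105 ± 23.5 CPM (log2 -2.17 ± 0.17), and the log2 changes of Id1 and Id2 were -1.57 ± 0.17 and -1.80 ± 0.18. Of the BMP and Id list 8 of 13 tested members fell (9 fell adjusted over the list alone, camera adjusted p = 6e-05, and adjusted p = 0.441 with an estimated correlation), with Hey1 at -1.49 ± 0.18 and Atoh8 at -2.84 ± 0.47. Angptl4, a secreted inhibitor of lipoprotein lipase, fell from 306 ± 18.1 to 44.8 ± 15.2 CPM (-2.77 ± 0.46). For the neural factor Pou3f2 the log2 change was -2.11 ± 0.28. In the list of proneural factors 4 of 14 tested members fell (5 fell adjusted over the list alone, camera adjusted p = 0.0152, and adjusted p = 0.593 with an estimated correlation), and that camera call was lost under library-size and depth scaling and without the 3 treated libraries of higher microglia level. At 1.5 h 0 of 14 were called (5 rose and 2 fell adjusted over the list alone, median log2 fold change 0.58, camera adjusted p = 0.216), and the level was 3.86 and 3.91 (log2 CPM) in replicates 1 and 2, 2.58 in replicate 3 and 2.83 to 3.21 in controls.

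Camera called the cell cycle lists lower at 3 h with the preset correlation, although most members did not pass the test and the libraries differed. Of the DNA replication list 8 of 20 tested members fell (11 fell adjusted over the list alone, camera adjusted p = 1.45e-06, and adjusted p = 0.588 with an estimated correlation), with the helicase subunit Mcm2 at -0.78 ± 0.14. Of the mitosis list 1 of 25 tested members fell (0 adjusted over the list alone, camera adjusted p = 6.73e-06, and adjusted p = 0.596 with an estimated correlation), and Mki67 was at 69.4 ± 98.7 CPM against 340.5 ± 36.8, which did not pass the test. The DNA replication level was 4.13 and 3.94 (log2 CPM) in replicates 1 and 2 and 5.57 in replicate 3, against 5.74 to 6.16 in controls. The mitosis level was 2.94 and 2.84 (log2 CPM) in replicates 1 and 2 of the 3 h group and 5.75 in replicate 3, against 6.01 to 6.46 in controls.

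Several stress and metabolic lists were called higher at 3 h by camera with the preset correlation. For NRF2 targets, antioxidant genes, 7 of 17 tested members rose (10 rose adjusted over the list alone, camera adjusted p = 0.000585, and adjusted p = 0.596 with an estimated correlation), with Srxn1, which repairs oxidised peroxiredoxins, at 1.98 ± 0.45, a call lost without control replicate 2 or replicate 2 of the 3 h group (0.93 to 2.25 over all settings). For the integrated stress response 11 of 21 tested members rose (14 rose adjusted over the list alone, camera adjusted p = 9.93e-05, and adjusted p = 0.544 with an estimated correlation). For p53 targets 9 of 18 tested members rose (10 rose adjusted over the list alone, camera adjusted p = 8.35e-05, and adjusted p = 0.441 with an estimated correlation). For NF-kB targets and cytokines 11 of 24 tested members rose (11 rose adjusted over the list alone, camera adjusted p = 0.00312, and adjusted p = 0.596 with an estimated correlation), with the adhesion molecule Icam1 at 0.95 ± 0.15. In glycolysis 7 of 15 tested members rose (8 rose adjusted over the list alone, camera adjusted p = 0.00184, and adjusted p = 0.588 with an estimated correlation), with the glucose transporter Slc2a1 at 1.78 ± 0.22. For CREB targets 11 of 17 tested members rose (11 rose adjusted over the list alone, camera adjusted p = 0.00102, and adjusted p = 0.441 with an estimated correlation). In the circadian clock list 9 of 14 tested members rose and 1 fell (10 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.00245, and adjusted p = 0.441 with an estimated correlation). Among short-lived mRNAs 10 of 22 tested members rose and 4 fell (12 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.0158, and adjusted p = 0.596 with an estimated correlation). For extracellular matrix 7 of 22 tested members rose (8 rose adjusted over the list alone, camera adjusted p = 0.000621, and adjusted p = 0.441 with an estimated correlation). Among reactive astrocyte genes 6 of 24 tested members rose (6 rose adjusted over the list alone, camera adjusted p = 0.0221, and adjusted p = 0.213 with an estimated correlation). In ribosome biogenesis 3 of 14 tested members rose (4 rose adjusted over the list alone, camera adjusted p = 0.0323, and adjusted p = 0.732 with an estimated correlation). Fibroblast and meningeal markers had the same median log2 change as the matrix list (0.753) and did not pass the test at 3 h (camera adjusted p = 0.166), and both lists were higher in replicates 1 and 2 (6.47 and 6.63 log2 CPM for fibroblast markers, 8.27 and 8.31 for matrix) than in replicate 3 (5.68 and 7.79). The NRF2 level was 10.48 and 10.37 in replicates 1 and 2 and 9.62 in replicate 3, against 9.24 to 9.45 in controls, and the integrated stress response level 7.55 and 7.47 against 6.20, with 5.75 to 5.93 in controls. The ribosome biogenesis call was lost in 7 of 14 settings, including without control replicate 3 and without replicate 1 or 2 of the 3 h group, and its direction turned in 1 setting. The calls for glycolysis, the integrated stress response and short-lived mRNAs were lost without the 6 libraries of lower microglia level, and that for NF-kB without the other 3 treated libraries.

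Together 2035 genes changed at 3 h against control, 1281 higher and 754 lower, and 770 changed 2-fold or more (572 higher and 198 lower). With depth scaling 677 were higher and 1718 lower. Without replicate 3 of the 3 h group 3697 genes were called, and without any other of the 6 libraries 849 to 1017. The median of all genes lay at -0.03 with the main scaling and at -0.31 with depth scaling, so changes at 3 h are relative to that choice, although no called gene turned direction between the 2.

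At 6 h many early genes were still above control, and the median log2 change of the BMP and Id list was -2.05, against -1.28 at 3 h. The level of this list was 5.58 to 5.68 (log2 CPM) in controls. At 3 h it was 4.03 in replicate 3, the library standing apart, against 4.88 and 4.76, and at 6 h 3.38 in replicate 1 against 3.91 and 3.95. Egr1 was at 226 ± 28.8 CPM (log2 2.74 ± 0.37) and Lif at 749 ± 103 CPM (3.78 ± 0.24). Of the immediate early list 23 of 25 tested members rose (24 rose adjusted over the list alone, camera adjusted p = 8.37e-10, and adjusted p = 0.655 with an estimated correlation). Among ERK feedback genes 13 of 15 tested members rose (13 rose adjusted over the list alone, camera adjusted p = 1.58e-06, and adjusted p = 0.444 with an estimated correlation). Among neurotrophic factors 9 of 18 tested members rose and 1 fell (11 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00231, and adjusted p = 0.459 with an estimated correlation). Of BMP and Id genes 10 of 13 tested members fell (10 fell adjusted over the list alone, camera adjusted p = 1.85e-07, and adjusted p = 0.632 with an estimated correlation). Smad9, a signal transducer of BMP receptors, fell from 66.6 ± 2.63 to 9.13 ± 0.594 CPM (-2.86 ± 0.21), Atoh8 from 72.7 ± 6.88 to 2.69 ± 1.70 CPM (-4.78 ± 0.53) and Id2 from 136 ± 13.3 to 24.5 ± 3.57 CPM (-2.48 ± 0.19).

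Several genes reached their highest level at 6 h. Aldh1a3, an enzyme of retinoic acid synthesis, rose from 4.59 ± 0.664 to 112 ± 55.3 CPM (log2 4.61 ± 0.69), the collagenase Mmp13 from 2.74 ± 1.74 to 48.3 ± 31.8 CPM (4.15 ± 0.96), and the chemokine Cxcl2 from 38.9 ± 4.91 to 196 ± 33.5 CPM (2.34 ± 0.34). For NF-kB targets and cytokines 13 of 24 tested members rose (13 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000856, and adjusted p = 0.916 with an estimated correlation), with Nfkb2 at 1.43 ± 0.18. For ribosome biogenesis 9 of 14 tested members rose (11 rose adjusted over the list alone, camera adjusted p = 0.00039, and adjusted p = 0.916 with an estimated correlation), with Nop56, a nucleolar protein, at 1.13 ± 0.25 and Rrp9 at 1.29 ± 0.21. For NRF2 targets 5 of 17 tested members rose (7 rose adjusted over the list alone, camera adjusted p = 0.0222, and adjusted p = 0.936 with an estimated correlation), a call lost without replicate 2 or replicate 3 of the 6 h group. For the integrated stress response 5 of 21 tested members rose and 1 fell (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0277, and adjusted p = 0.916 with an estimated correlation). For extracellular matrix 7 of 22 tested members rose (7 rose adjusted over the list alone, camera adjusted p = 0.00756, and adjusted p = 0.916 with an estimated correlation). In the circadian clock list 5 of 14 tested members rose (5 rose adjusted over the list alone, camera adjusted p = 0.0277, and adjusted p = 0.916 with an estimated correlation), a call lost without control replicate 2.

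Among the genes lower at 6 h, Lmod1, an actin-binding protein, fell from 17.8 ± 6.80 to 0.854 ± 0.0764 CPM (-4.36 ± 0.59), Angptl4 to 19.8 ± 15.6 CPM (-3.94 ± 0.49) and Pdk4 to 1.14 ± 0.264 CPM (-4.11 ± 0.26). Of DNA replication genes 8 of 20 tested members fell (15 fell adjusted over the list alone, camera adjusted p = 2.67e-06, and adjusted p = 0.916 with an estimated correlation), with Mcm4 at -1.20 ± 0.27. Among mitosis genes 2 of 25 tested members fell (0 adjusted over the list alone, camera adjusted p = 3.93e-06, and adjusted p = 0.916 with an estimated correlation). The DNA replication level at 6 h was 5.35 (log2 CPM) in replicate 1 and 4.01 and 3.96 in replicates 2 and 3. The mitosis levels at 6 h were 5.73 (log2 CPM) in replicate 1 and 2.50 and 2.71 in replicates 2 and 3. Of proneural factors 5 of 14 tested members fell (5 fell adjusted over the list alone, camera adjusted p = 0.0233, and adjusted p = 0.916 with an estimated correlation). Among these 6 h lists the matrix, clock and NRF2 calls were lost without the 6 libraries of lower microglia level, the integrated stress response call with the microglia covariate and the proneural call with library-size scaling.

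At 6 h 2891 genes had changed against control, 1771 higher and 1120 lower, with 1099 at 2-fold or more (714 higher and 385 lower). With depth scaling 1235 were higher and 1712 lower. Leaving out 1 control library gave 1754 to 1862 calls, and leaving out replicate 2 or 3 of the 6 h group 1741 or 1745. Groups did not overlap in any library for 28.1%, 47.6% and 55.7% of the 9491 genes at 1.5, 3 and 6 h, where chance gives 10%. That 10% holds only for independent libraries and for genes not chosen for differing between groups. The labels say neither, and the make-up of the table puts the second in doubt.

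**Figure D3:**
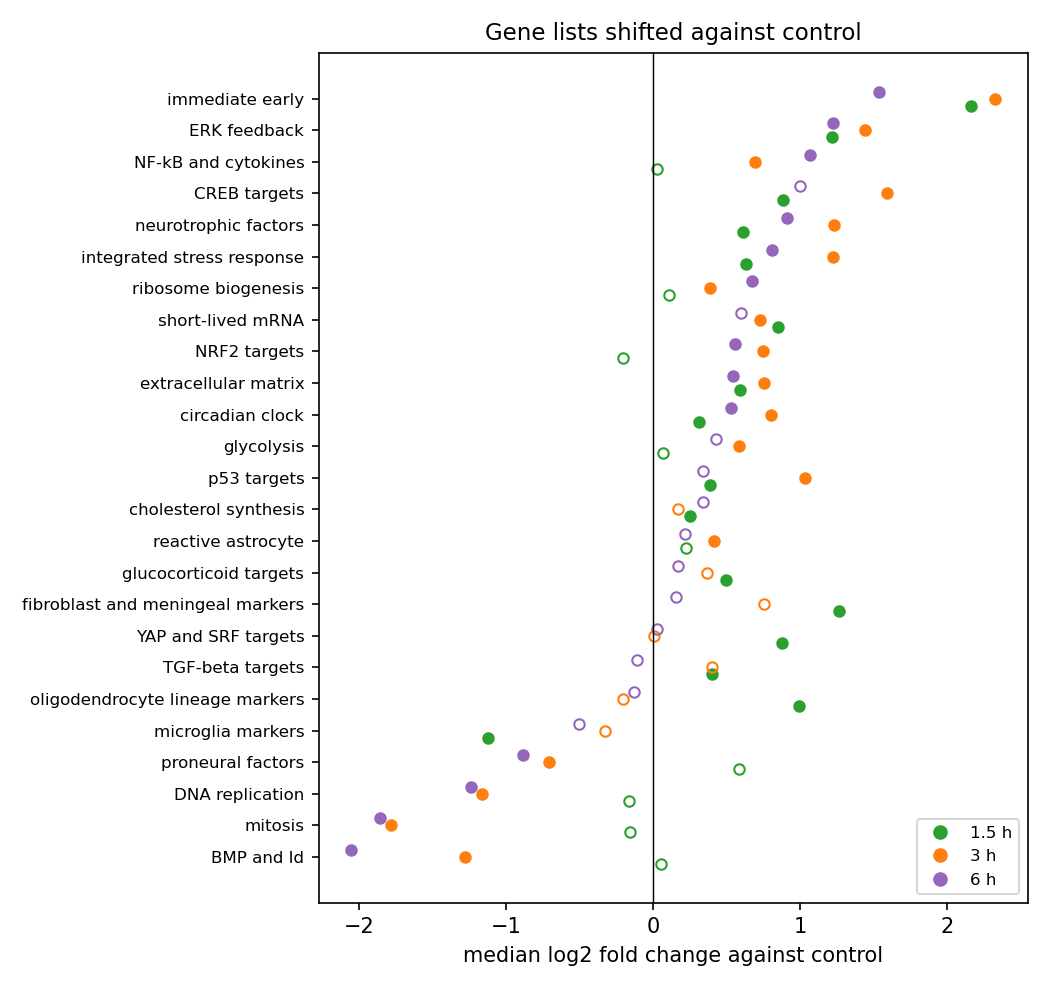
Median log2 fold change against control of the 25 gene lists that camera called at 1 or more times, at 1.5 h (green), 3 h (orange) and 6 h (purple). Filled points had a camera adjusted p below 0.05 with the preset correlation. The immediate early list lay highest, at 2.33 at 3 h, and the BMP and Id list lowest, at -2.05 at 6 h.

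Most genes that mark astrocytes did not pass the test. Of the astrocyte identity list, 0 of 15 were called (0 adjusted over the list alone, median log2 fold change 0.27, camera adjusted p = 0.17) at 1.5 h. At 3 h 2 of 15 rose (2 rose adjusted over the list alone, median log2 fold change 0.21, camera adjusted p = 0.166). At 6 h 1 of 15 rose and 3 fell (1 rose and 3 fell adjusted over the list alone, median log2 fold change -0.16, camera adjusted p = 0.691). Gfap, the astrocyte intermediate filament, was at 2180 ± 458 CPM in controls and 3146 ± 209.7, 1772 ± 594 and 1206 ± 319.7 CPM at 1.5, 3 and 6 h, and passed the test at 6 h with a log2 change of -0.85 ± 0.27. That call was lost without any 1 of the control libraries or without replicate 2 or 3 of the 6 h group (log2 changes from -1.17 to -0.49 over all settings). The transcription factor Nfib was lower at 6 h (-0.76 ± 0.13). Sox9 rose at 3 h from 119.6 ± 11.4 to 257 ± 8.99 CPM (1.10 ± 0.12). The water channel Aqp4, with 1543 ± 514 CPM in controls and 878 ± 259 at 6 h, did not pass the test.

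Several progenitor transcription factors were lower at the later times. Sox2 (ENSRNOG00000012199), a factor of neural stem cells, went from 173 ± 2.38 CPM to 64.9 ± 4.34 at 3 h and 68.2 ± 3.60 at 6 h (log2 -1.42 ± 0.16 and -1.35 ± 0.16). Pax6 changed by -0.91 ± 0.19 and -0.91 ± 0.19, and Nr2e1 by -1.19 ± 0.15 at 6 h. Of the neural progenitor list, 1 of 14 fell (1 fell adjusted over the list alone, median log2 fold change 0.18, camera adjusted p = 0.218) at 1.5 h. At 3 h 2 of 14 rose and 4 fell (2 rose and 4 fell adjusted over the list alone, median log2 fold change -0.04, camera adjusted p = 0.57). At 6 h 1 of 14 rose and 5 fell (2 rose and 5 fell adjusted over the list alone, median log2 fold change -0.10, camera adjusted p = 0.278).

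The list of neuronal genes did not pass camera's test at any time. Of the list of neuronal structure and synapse genes, 0 of 22 were called (0 adjusted over the list alone, median log2 fold change 0.48, camera adjusted p = 0.0589) at 1.5 h, when the level was 5.22 and 5.24 (log2 CPM) in replicates 1 and 2, 4.33 in replicate 3 and 4.24 to 4.75 in controls. At 3 h 1 of 22 rose (0 adjusted over the list alone, median log2 fold change -0.18, camera adjusted p = 0.608). At 6 h 1 of 22 rose and 1 fell (1 rose adjusted over the list alone, median log2 fold change -0.08, camera adjusted p = 0.679). Tubb3, a neuronal tubulin, was called higher at 3 and 6 h (log2 1.51 ± 0.42 and 1.70 ± 0.42). Its 3 h call was lost without any 1 of the 3 controls or replicate 1 or 2 of the 3 h group (0.53 to 1.76 over all settings), and its 6 h call without control replicate 3. Its libraries split with the microglia level, with 71.8 CPM in replicate 3 and 182.5 and 167 CPM in replicates 1 and 2 at 3 h. Dcx was at 12.3 ± 4.22 CPM in controls and 1.65 ± 2.50 at 6 h, and Map2 at 102 ± 6.23 and 79.4 ± 18.0, and neither passed the test. For midbrain dopaminergic factors 1 of 7 rose (1 rose and 1 fell adjusted over the list alone, median log2 fold change 0.43, camera adjusted p = 0.238) at 1.5 h, and 3 of 7 rose (3 rose adjusted over the list alone, median log2 fold change 0.78, camera adjusted p = 0.101) at 3 h. At 6 h 1 of 7 rose and 1 fell (1 rose and 1 fell adjusted over the list alone, median log2 fold change 0.49, camera adjusted p = 0.691), with Wnt5a, a secreted signal, at 1.26 ± 0.24 at 6 h. Nr4a2, a dopaminergic factor, was at 6.20 ± 1.38 CPM in controls and 32.3 ± 21.8 at 3 h (2.38 ± 0.60), a call lost without any 1 control or replicate 1 or 2 of the 3 h group (0.22 to 2.80 over all settings). For dopamine synthesis and transport 1 of 7 rose (1 rose adjusted over the list alone, median log2 fold change 0.44, camera adjusted p = 0.168) at 1.5 h, 0 of 7 were called (0 adjusted over the list alone, median log2 fold change 0.38, camera adjusted p = 0.57) at 3 h, and 1 of 7 rose (1 rose adjusted over the list alone, median log2 fold change -0.04, camera adjusted p = 0.988) at 6 h.

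Ptbp1 (ENSRNOG00000010448), the splicing repressor whose loss has been tied to neuronal conversion, was at 604 ± 33.5 CPM in controls and 601 ± 21.5, 562 ± 27.6 and 559.7 ± 25.0 at 1.5, 3 and 6 h. Its log2 change at 6 h was -0.11 ± 0.11, which did not pass the test. Rest, a repressor of neuronal genes, rose from 45.3 ± 1.80 CPM to 79.4 ± 7.15 and 73.0 ± 5.04 (0.81 ± 0.11 and 0.69 ± 0.11). For the PTB and REST list 1 of 17 rose and 2 fell (1 rose and 2 fell adjusted over the list alone, median log2 fold change -0.10, camera adjusted p = 0.608) at 3 h. At 6 h 3 of 17 rose and 1 fell (3 rose and 1 fell adjusted over the list alone, median log2 fold change -0.11, camera adjusted p = 0.927).

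**Figure D4:**
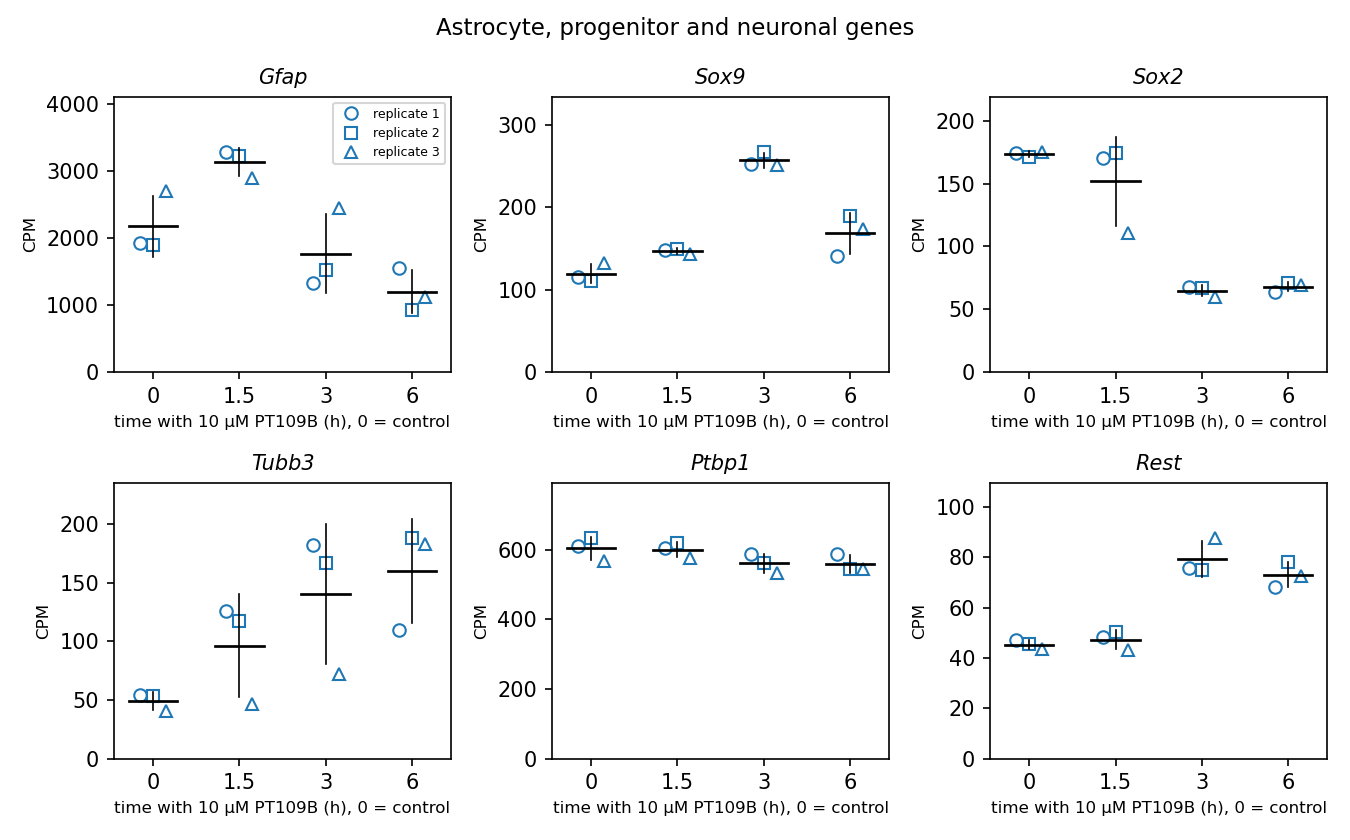
CPM of 6 astrocyte, progenitor and neuronal genes in each library against hours with 10 µM PT109B (0 is control). Symbols are libraries, with shapes for the replicate number, horizontal lines are group means and vertical lines are SD. Sox2 was lower and Rest higher at 3 and 6 h than in every control library, whereas Tubb3 differed between libraries of a group and Ptbp1 lay between 534 and 635 CPM.

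The treated groups were also compared directly. Between 1.5 and 3 h 1929 genes changed (1148 higher and 781 lower at 3 h), between 3 and 6 h 384 changed (221 and 163), and between 1.5 and 6 h 3571 changed (1946 and 1625). In fits of only the 2 groups compared 76, 7 and 2142 genes were called. With depth scaling the higher and lower counts were 614 and 1339, 385 and 133, and 1578 and 1884, so the direction of the majority turned between 1.5 and 3 h and between 1.5 and 6 h. From 1.5 to 6 h Egr1 changed by -2.26 ± 0.36, Arc by -4.11 ± 0.33 and Fos by -2.24 ± 0.27. From 3 to 6 h Smad9 fell further (-1.72 ± 0.20), as did Nr2e1 (-0.63 ± 0.15), and Cry1 rose (0.60 ± 0.12). Without replicate 3 of the 1.5 h group 4051 genes changed between 1.5 and 3 h, without replicate 3 of the 3 h group 3464, and without any other of the 6 libraries 422 to 539. Between 3 and 6 h the count was 788 without replicate 3 of the 3 h group and 41 to 68 without replicate 1 or 2 of the 3 h group or replicate 2 or 3 of the 6 h group. Between 1.5 and 6 h it was 2257 to 2340 without replicate 1 or 2 of the 1.5 h group or replicate 2 or 3 of the 6 h group. With the replicate number as a block 1243 and 159 genes changed between 1.5 and 3 h and between 3 and 6 h.

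Over the time course 3875 genes differed among the groups, against 6201 without replicate 3 of the 1.5 h group and 2613 to 5629 without any other library. By the direct tests, 168 genes were early and returning, that is called at 1.5 h and changed in the opposite direction from 1.5 to 6 h. Another 2035 were late, called at 6 h and not at 1.5 h with a difference in the same direction between these times, and 96 were sustained at all 3 times with no difference called between 1.5 and 6 h. Egr1, Fos and Per2 were early and returning, Sox2, Id3 and Aldh1a3 were late, and Lif, Pdgfb and Ptgs2 were sustained. Without replicate 3 of the 1.5 h group the early and returning class held 2039 genes and the sustained class 302, and without 1 control or another library of the 1.5 h group 61 to 68 and 41 to 57. Without replicate 2 or 3 of the 6 h group the late class held 1185 or 1199 genes and the early and returning class 106 or 103. With the replicate block 99 genes were early and returning.

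Fold changes at 3 and 6 h correlated across genes with r = 0.85, at 1.5 and 3 h with r = 0.44 and at 1.5 and 6 h with r = 0.29 (genes are not independent replicates). Unchanged groups simulated against 3 shared controls, which were simulated too, gave r = 0.49, 0.50 and 0.50. The covariances were 0.658, 0.243 and 0.177 against simulated values of 0.0883, 0.0895 and 0.0889. The simulated spread was estimated over all groups together. Real controls were more alike (r of 0.9887 to 0.9949 between libraries) than libraries at 1.5 h (r down to 0.9176). The simulated values may therefore overstate what the real controls contribute, and they do not measure it. Of the genes called higher, 976 were shared by 3 and 6 h where independent lists would share 239, and 158 by 1.5 and 3 h where 25 would be shared. For genes called lower these were 442 against 89, and 58 against 10.3. Between 1.5 and 6 h 125 higher and 28 lower genes were shared, against 34.5 and 15.3. Part of the excess may come from the shared controls, which were too few to split.

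The remaining lists fixed before the data were examined gave no camera call at any time. Of Wnt targets, 2 of 8 rose (2 rose adjusted over the list alone, median log2 fold change 0.48, camera adjusted p = 0.515) at 6 h, with the called genes Lef1 (2.08 ± 0.36) and Tcf7 (1.09 ± 0.24). Of interferon response genes 1 of 21 rose (1 rose adjusted over the list alone, median log2 fold change -0.40, camera adjusted p = 0.443), the riser being Oasl (4.09 ± 0.79). Libraries of a group differed in this list. The library standing apart was at 5.23, 4.57 and 4.71 (log2 CPM) at 1.5, 3 and 6 h. The other pair was at 2.87 and 3.09, 2.92 and 2.8, and 3.32 and 3.33, with 3.95 to 4.82 in controls. The counts that follow are again for 6 h. Of hypoxia genes 3 of 14 rose and 1 fell (3 rose and 1 fell adjusted over the list alone, median log2 fold change 0.16, camera adjusted p = 0.578), with Ndrg1 at 2.43 ± 0.26. Of AhR targets 3 of 8 rose and 1 fell (3 rose and 1 fell adjusted over the list alone, median log2 fold change 0.08, camera adjusted p = 0.917), with Nfe2l2 higher (0.89 ± 0.15) and Cyp1a1 lower (-1.25 ± 0.16). Of Notch targets 3 of 13 rose and 3 fell (4 rose and 5 fell adjusted over the list alone, median log2 fold change -0.001, camera adjusted p = 0.705). Of ER chaperones 1 of 12 rose and 2 fell (1 rose and 2 fell adjusted over the list alone, median log2 fold change -0.17, camera adjusted p = 0.515). Of heat shock genes 1 of 12 rose and 3 fell (1 rose and 3 fell adjusted over the list alone, median log2 fold change 0.23, camera adjusted p = 0.988). Metallothionein and metal genes, fatty acid and LXR genes, electron transport genes and mitochondrially encoded genes had median log2 changes of 0.31, -0.10, -0.07 and 0.12 at 6 h. Endothelial and mural cell markers had medians of -0.57 and -0.67. The ribosomal protein and ependymal lists held 2 tested genes each and were not tested as lists.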

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

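The tests of the 3 patterns weighed here were chosen only after the patterns were seen, while the differences between times and the counts over other splits of the libraries were planned.

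Effects against control differed between times in direct tests by edgeR's quasi-likelihood test. Between 1.5 and 3 h 1929 genes differed, between 3 and 6 h 384, and between 1.5 and 6 h 3571. In fits of only the 2 groups compared these counts were 76, 7 and 2142. Over all tested genes 18 were called in opposite directions at 1.5 and 6 h, and 2 of these were named by rule. Irs3, an insulin receptor substrate, changed by -1.16 ± 0.28 at 1.5 h and 0.86 ± 0.27 at 6 h (difference 2.01), and its 1.5 h call was lost in 9 of 14 settings, including without any 1 control or replicate 1 or 2 of the 1.5 h group (-1.43 to -0.74 over all settings). Ddit4, an inhibitor of mTOR signalling, changed by 1.12 ± 0.16 and -0.64 ± 0.16 (difference -1.77), and its 6 h call was lost without control replicate 3, replicate 3 of the 6 h group or the 6 libraries of lower microglia level (-0.85 to -0.47 over all settings).

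In each treated group 2 libraries were nearly alike and 1 stood apart. An untreated library with a wrong label is argued against, because the 3 libraries standing apart exceeded the highest control in immediate early level by at least 1.22 (log2), although a wrong time label stays open. More RNA from microglia in the library standing apart than in the pair, as the whole cause of the 1.5 h split, is argued against. It would dilute the markers of other cell types alike. Differences between the library standing apart and the other pair ran from -1.61 for oligodendrocyte to 1.45 for endothelial markers, a span of 3.06 (log2) over 5 lists, against at most 0.71 for a control library. At 1.5 h the pair departed from control and the library standing apart lay near it. Microglia markers were at 3.85 and 3.78 (log2 CPM) in the pair, 7.13 in the other library and 6.77 to 7.04 in controls. Oligodendrocyte markers were at 5.65 and 5.77, 4.1 and 3.93 to 4.39 in the same order. Endothelial markers were low, at 1.16 and 1.1, 2.58 and 2.4 to 2.6. A part from microglia stays open, as does a change in the other cell types. At 3 and 6 h the mitosis difference exceeded the microglia difference by at least 2.27 (log2), which argues against microglia as the whole cause there. A shared batch across 3 and 6 h is in line with r = 0.79 across genes between the differences at these times, and one reaching 1.5 h rests on r = 0.22. Across genes the deviation of control replicate 3 from its group correlated with that of replicate 3 at 1.5 h (r = 0.451). It did not correlate with that of replicate 3 at 3 h (-0.027) or replicate 1 at 6 h (-0.015). The labels give no batch, the sets of libraries were found in the data, and no biological explanation was tested.

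Immediate early genes lay above control at all times. Scaling is argued against, since 23 of them were called higher at 3 h with depth scaling. Another mix of cells in the libraries with lower microglia levels, as the whole cause, is argued against too. All 25 genes exceeded the highest control in each of the 3 treated libraries with control-like microglia levels. A mix of cells that does not follow the microglia level was not tested. Handling at the start of treatment cannot be told apart from the compound, because the labels give no time-matched vehicle group, and the median change at 6 h was 1.54 (log2). The compound itself stays among the open explanations.

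Most genes were lower at 3 h when libraries were scaled by depth. The median log2 change was -0.311 with this scaling and -0.34 with library size, and these scalings are not independent. Both set each gene against the reads of the whole library, so neither measures RNA per cell. The median shift was -0.44 and -0.41 (log2) in replicates 1 and 2 and -0.10 in replicate 3, so a difference between libraries rather than a change with time may be the source. A change with time that the library standing apart did not share stays open.

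Other splits of the libraries were counted. For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. By edgeR the real split gave 315, 2035 and 2891 genes at 1.5, 3 and 6 h and 1929, 384 and 3571 between times, and the highest of the other splits gave 0 in each case, so 1 split in 10 was as large. Camera called 16, 18 and 13 lists with the real split and 17, 20 and 15 with the highest other, with 2, 3 and 3 splits as large. For the time course the real grouping gave 3875 genes and was the only 1 of 100 that large, the highest other giving 1170. Chance can be excluded there only if the libraries are independent and the genes of the table were not chosen for differing between groups. The labels say neither, and the make-up of the table puts the second in doubt.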

How the results depend on the processing

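The depth scaling, the microglia covariate, the sets of libraries by microglia level, the fixed reference library and the counts of called list members were chosen only after the results were seen. Over 633 named genes at a time and their alternatives, 7429 of 8862 values kept both their sign and their side of the threshold. With the sign kept, 697 lost and 365 gained a call. Another 371 without a call in the main test changed sign, and 0 changed direction among called values. Other scaling (library size and depth among them), filters, thinning, non-robust fits, limma-voom and limma-trend on FPKM kept the counts of called genes within 1.5 times the main ones (1.5 h: 278 to 392 genes). Similar counts did not mean the same genes or directions. At 3 h the main test called 1281 higher and 754 lower. Library-size scaling called 650 higher and 1887 lower, sharing 1404 genes with the main 2035. Limma-trend on log2(FPKM + 1) called 676 higher and 2077 lower, sharing 1397. A fold threshold asks for more evidence by construction, and the cause of the other changes below was not tested.

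With the replicate number as a block 201 genes were called at 1.5 h, 1243 between 1.5 and 3 h, 159 between 3 and 6 h and 99 as early and returning, and the other counts stayed within 1.5 times. Of 18 pairs of libraries with the same number 8 correlated with r over 0.1 (-0.657 to 0.599), and 6 of 12 libraries matched their own number best, so the numbers do not pair the libraries across all groups. Same-number pairs of control with 1.5 h had r of 0.2, 0.368 and 0.451, and of 1.5 h with 3 h 0.179, 0.166 and 0.224. Those of control with 3 h had 0.035, -0.023 and -0.027, and of 3 h with 6 h -0.651, 0.599 and -0.657. Some pairs of unlike number were as high (0.211 for control replicate 1 with replicate 2 at 1.5 h). Pairing in some groups stays open. With glmTreat at a fold of 1.2 the counts were 156, 1030 and 1895 at 1.5, 3 and 6 h, 735 between 1.5 and 3 h and 99 between 3 and 6 h. In fits of only the 2 groups 76, 7 and 2142 genes differed between 1.5 and 3, 3 and 6, and 1.5 and 6 h. DESeq2 called 788 genes at 1.5 h, 118 list members at 1.5 h and 838 genes between 3 and 6 h. With an estimated correlation 0 lists passed at each time in camera, against 16, 18 and 13 with the preset one and 11, 22 and 15 in fry.

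With the microglia level as a covariate 176 genes were called at 1.5 h, 1133 between 1.5 and 3 h, 982 between 3 and 6 h, 99 as early and returning and 55 as sustained, and the correlations of fold changes were 0.265 (1.5 and 3 h) and 0.196 (1.5 and 6 h). Without the 3 treated libraries of higher microglia level the counts were 5642, 6756 and 7154 at 1.5, 3 and 6 h (list members 445, 501 and 487), 6655 between 1.5 and 3 h, 3251 between 3 and 6 h, 7242 between 1.5 and 6 h, 9303 over the time course, 3493 early and returning and 858 sustained, with correlations of 0.302 and 0.240. Without the 6 of lower level they were 383, 14 and 1600 between 1.5 and 3, 3 and 6, and 1.5 and 6 h, 2499 over the time course and 1231 late, with correlations of 0.506, 0.359 and 0.698. Lone treated libraries were there assumed to vary like the controls. Within the 4 libraries of lower level at 3 and 6 h 4191 genes differed.

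Leaving out each replicate gave 115 to 2871 genes at 1.5 h, 849 to 3697 at 3 h, 1741 to 3868 at 6 h, 422 to 4051 between 1.5 and 3 h, 41 to 788 between 3 and 6 h, 2257 to 5002 between 1.5 and 6 h and 2613 to 6201 over the time course. The early and returning, late and sustained classes held 61 to 2039, 1185 to 2840 and 41 to 302 genes. Called list members numbered 47 to 234, 114 to 307 and 129 to 266 at 1.5, 3 and 6 h against 75, 194 and 204 with all libraries. Lists called numbered 16 to 18, 17 to 20 and 12 to 13. The correlations of fold changes were 0.298 to 0.5 (1.5 and 3 h), 0.221 to 0.337 (1.5 and 6 h) and 0.778 to 0.853 (3 and 6 h). Thinned to the smallest library 293, 2004 and 2861 genes were called at 1.5, 3 and 6 h, and limits by depth at each expression level were not analysed here.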

Other observations

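The enrichment of splicing genes was tested on a hypothesis written before its result was seen, and the other terms below were chosen after all 1744 were tested.

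Gene Ontology terms were tested besides the fixed lists, and several of them overlap those lists in subject. Among genes higher at 6 h, 24 of 37 ribosome biogenesis genes were called where 6.9 were expected (Fisher's exact test, adjusted p = 1.31e-06), and 21 of 47 genes of canonical Wnt signaling where 8.8 were expected (Fisher's exact test, adjusted p = 0.0155). The terms with the smallest p among genes lower at 6 h were cellular response to DNA damage stimulus (67 of 247 genes, expected 29.8, Fisher's exact test, adjusted p = 9.28e-08), DNA repair (44 of 159, expected 19.2) and DNA replication (27 of 75, expected 9.1, both with an exact test adjusted p = 3.91e-05). At 3 h 52 of 247 genes of the DNA damage term were lower (expected 19.7, exact test adjusted p = 7.14e-08). The DNA replication list differed between libraries of a group, at 5.35, 4.01 and 3.96 (log2 CPM) in the 6 h libraries. Also lower at 6 h were 35 of 130 genes of cilium morphogenesis (expected 15.7, Fisher's exact test, adjusted p = 0.00119) and 17 of 46 of smoothened signaling (expected 5.6, adjusted p = 0.00428 in the exact test). Genes of negative regulation of neuron differentiation were lower in 15 of 47 cases (expected 5.7, exact test adjusted p = 0.0426). At 3 h 16 of 30 genes of the response to cAMP were higher (expected 4.1, exact test adjusted p = 0.000475), and at 1.5 h 7 of 26 genes of negative regulation of MAPK cascade (expected 0.5, exact test adjusted p = 0.000416). Counts of genes over-represented this way treat genes as independent, which they are not.

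Because Ptbp1 is a splicing regulator, genes of RNA splicing were tested for over-representation among genes lower at 6 h. The odds ratio was 1.785 with 18 of 92 genes called (Fisher's exact test, one-sided, p = 0.02516, adjusted p = 0.510 over 1744 terms), so it did not pass the adjusted threshold set for it. At 3 h 17 of 92 genes of this term were lower (odds ratio 2.662, exact test p = 0.0008281, adjusted p = 0.103). A narrower term, mRNA splicing via the spliceosome, had 17 of 73 genes lower at 3 h (expected 5.8, exact test adjusted p = 0.00934), which was not the term or time of the written hypothesis.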
